A study of Homo sapiens with 12 samples.

How the data were processed

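RNA of the human colon cancer line LS411N and of its derivative LS411N-BR, which tolerates BRAF inhibitors and was kept in 4 µM of such an inhibitor, was sequenced by the submitters after TruSeq Stranded mRNA library preparation. Both lines carried a doxycycline-inducible short hairpin RNA against MUC1. Each line was grown with 500 ng/ml doxycycline or without it, with 0.1% DMSO as the vehicle, in triplicate, which gives 4 groups of 3 libraries and 12 libraries. Whether the triplicates were grown on separate days is not given in the sources used here. Nor are the hairpin sequence, the duration of doxycycline or the identity of the inhibitor.

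The deposited values are TPM per gene, in 1 table per line. Each library summed to 1000000 TPM. STAR, DESeq2 and GRCh38 are named per the submitters' processing notes, without roles. The program that made the TPM and its annotation are not given in the sources used here, and neither are read totals, so the depth per library is unknown and no interval for counting error is given. The table of LS411N lists 25673 genes and that of LS411N-BR 25540, all of them also in the LS411N table. Of the 133 genes listed for LS411N alone, 77 are short RNA genes, and SNORD3A alone took between 6.64 and 12.8% of the TPM of an LS411N library. TPM of the lines are therefore scaled over different genes. Symbols were matched to RefSeq names for 23345 genes, and positions, gene types and untranslated regions came from GENCODE 29 on GRCh38.

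Changes with doxycycline were tested per line with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(TPM + 1). Genes with at least 1 TPM in at least 3 of the libraries compared were tested, two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The difference of the doxycycline effect between the lines was the interaction term of a limma fit over all 12 libraries. All log2 fold changes are on the log2(TPM + 1) scale, which shrinks those of genes with few TPM. In LS411N-BR the prior degrees of freedom were infinite, so every gene took the spread of the trend at its level and the p-values of that line are very small. The direction of calls shared by the lines was counted among genes tested in both, with Fisher's exact test. The test between the lines without doxycycline was planned only for libraries scaled over the same genes, so their levels are given side by side after rescaling over shared genes, without a test.

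Gene lists, 33 in all, were tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, where at least 5 members were tested. That left 30 lists in each comparison. Not every listed symbol was matched to a gene in the tables. Matched were 32 of 37 in the ATF4 list, 38 of 46 in nuclear oxidative phosphorylation and 6 of 20 in histones. A list's median log2 fold change is relative to the median of all tested genes where it is said to lie above or below. Otherwise it is the list's own median unless stated. Samples, groups, tests, lists and the rule for named genes were fixed before the data were examined. The rule takes MUC1 first. It then takes the 8 genes with the largest change in each direction (5 for the difference between lines) among called genes whose groups do not overlap and whose higher group has a mean of at least 5 TPM. Clone-based and LOC-type symbols, pseudogenes, XIST and Y-linked genes were passed over. Some of the genes that the rule takes are not reported here and were not replaced. Last come up to 3 members with the smallest adjusted p of each list that was called or had at least 5 called members.

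Recovery was tested on simulated data with the same number of libraries and similar spreads. Changes of 2-fold were recovered for 100% of genes in every comparison, and changes of 1.5-fold for 64.2% in LS411N, 100% in LS411N-BR and 58.2% in the difference between lines. False calls made up 4.35%, 2.91% and 2.82% of the calls. The noise was drawn for each gene independently, with no shift shared by the genes of a library. For the difference, all groups started from the levels of LS411N-BR without doxycycline. These shares therefore do not cover shifts that genes share in the real libraries. For gene lists, the WNT targets were shifted by 0.5 on the log2 scale in simulated LS411N-BR libraries. Camera called that list and 1 other of 30. Lists can share members, as the WNT target and stem cell lists do with EPHB2 and EPHB3, so their calls are not independent.

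Other settings fixed beforehand were a pseudocount of 0.1 TPM, no filter except a value above 0, a filter of 5 TPM, median-of-ratios rescaling between libraries, no trend, robust moderation, leaving out each library, the replicate number as a covariate, a spread from all 12 libraries, and camera with an estimated correlation. Settings added after seeing the data were rescaling over protein-coding genes or over the genes shared by the tables, leaving out replicate 3 of LS411N without doxycycline together with median-of-ratios rescaling, and leaving out genes with certain 3′ UTR words. Rescaling, also with an estimated correlation, leaving out that replicate and the smaller pseudocount were added for the gene lists, and median-of-ratios rescaling for the calls shared by the lines. The count of genes with a gap of at least 4-fold between the lines was chosen after seeing the data too.

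Those words came from a search, run because an induced hairpin can act on other mRNAs through its seed. For each of the 16384 words of 7 bases, the log2 fold changes after median-of-ratios rescaling were regressed on the word's presence. Presence was taken in the longest annotated 3′ UTR of each gene, with the log length of the UTR and its square as covariates. Log2 fold changes were limited to 2 in size, UTRs had at least 50 bases and words were held by at least 50 genes. The search ran in Python 3.11.15 with numpy 2.4.6. The words with the most negative statistics were ATCAGTA in LS411N and TCAGTAA in LS411N-BR. Genes whose 3′ UTR holds either are called genes with a word below, and this is stated beside the named ones. Other splits of the same libraries were refitted, all 10 within a line and 100 drawn splits for results that use both lines. Figures were drawn with matplotlib 3.10.9.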

Results

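The data are RNA-seq profiles of LS411N, a human colon cancer line, and LS411N-BR, its derivative resistant to BRAF inhibitors, each with and without doxycycline induction of a MUC1 hairpin (3 libraries per group). Between 15116 and 17999 genes had a value above 0 in a library. Short RNA genes took 54.5% ± 6.26 (SD, n = 3) of the TPM in LS411N without doxycycline and 54% ± 2.11 with it, and 53.5% ± 1.03 and 49.7% ± 2.1 in LS411N-BR. Replicate 3 of LS411N without doxycycline stood apart, with 47.29% short RNA against 58.19% and 58.09% in the other 2 libraries of its group. The SD of its log2 differences to them was 0.19 and 0.196, against 0.072 to 0.123 in the other 10 pairs of replicates. All values below are mean TPM ± SD over 3 libraries unless stated.

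MUC1, which encodes a transmembrane mucin whose C-terminal subunit is the target in the series title, fell in both lines. In LS411N it went from 5.09 ± 0.875 to 0.922 ± 0.094 TPM, 81.9% lower (log2 fold change -1.66 ± 0.13 SE, adjusted p = 3.5e-14). In LS411N-BR it went from 3.97 ± 0.293 to 0.509 ± 0.166 TPM, 87.2% lower (-1.72 ± 0.08 SE, adjusted p = 5e-108). Every library with doxycycline lay below every library without it. A word lies in 16 annotated MUC1 transcripts, as coding sequence in 13 of them and outside it in 3, and the longest annotated 3′ UTR, the one searched, holds it. The effect on MUC1 was not shown to differ between the lines (difference -0.07 ± 0.15 SE, adjusted p = 0.87). The gene lies on the minus strand of chromosome 1 from 155185824 to 155192916 (GRCh38).

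**Figure D1:**
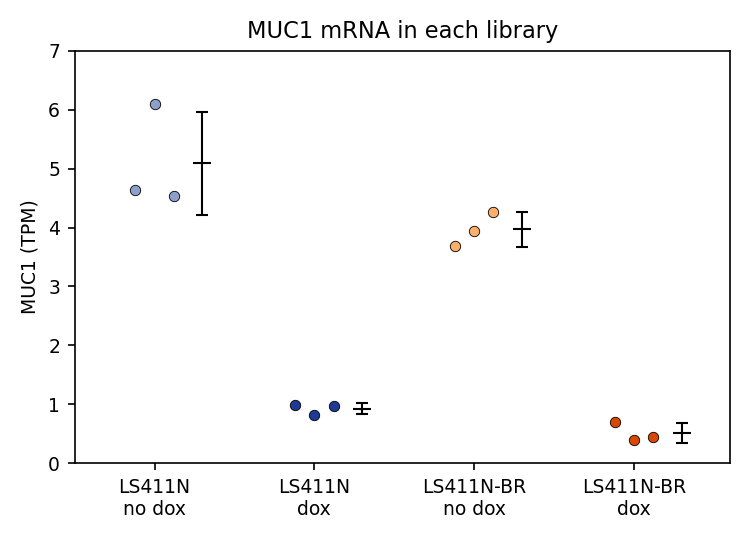
MUC1 mRNA in TPM (vertical axis) in each of the 12 libraries, by line and doxycycline. Points are libraries, and the bars beside them are the mean and SD of 3 libraries. Libraries with doxycycline lie between 0.388 and 0.986 TPM and those without between 3.69 and 6.1 TPM.

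The first comparison asked which mRNAs changed when the hairpin was induced in LS411N. FABP1, a fatty acid binding protein of absorptive cells, rose from 6.84 ± 2.19 to 39.1 ± 4.03 TPM, and KRT20, a keratin of the upper crypt, from 3.64 ± 1.21 to 17.3 ± 0.921 TPM. The epithelial membrane protein EMP1 had the largest rise of the named genes on the log2(TPM + 1) scale, from 5.29 ± 0.672 to 44.1 ± 1.92 TPM (log2 fold change 2.85 ± 0.14 SE). SMOC2, a marker of intestinal stem cells, fell from 94.3 ± 9.64 to 5.85 ± 0.155 TPM (-3.79 ± 0.14 SE), and PLA2G2A, a secreted phospholipase, from 1210 ± 94.7 to 137 ± 12.8 TPM. FABP1, EMP1 and SMOC2 had adjusted p-values of 1.4e-16, 7.6e-21 and 2.2e-25.

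Of 11281 genes tested in LS411N, 1100 were called higher and 387 lower with doxycycline, 90 and 38 of them by at least 2-fold. The median over all tested genes was 0.08 on the log2 scale. With median-of-ratios rescaling 2126 genes were higher and 1804 lower, so the share of calls that were higher went from 74 to 54.1%, and 1029 and 379 genes were called in the same direction under both scalings. Without replicate 3 of LS411N without doxycycline, 5938 genes were higher and 739 lower, of which 1089 and 378 were also called with it. Leaving out any other single library gave 523 to 647 genes higher and 174 to 425 lower, with 174 without replicate 3 and 253 without replicate 2 of LS411N with doxycycline.

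Among the other genes with the largest changes, ANXA1, an annexin, rose from 20.8 ± 4.11 to 116 ± 7.14 TPM, and COL17A1, a hemidesmosome collagen, from 5.57 ± 1.1 to 26.6 ± 2.32 TPM. MMP1, a collagenase, rose from 0.751 ± 0.127 to 6.88 ± 0.646 TPM, PI3, an elastase inhibitor, from 3.97 ± 0.496 to 19.2 ± 3 TPM, and RAB27B, a GTPase of secretory vesicles, from 1.74 ± 0.451 to 10.2 ± 0.401 TPM. SNORA74B, a small nucleolar RNA, rose from 16.1 ± 14.2 to 43 ± 11.3 TPM, a call lost with median-of-ratios rescaling and without replicate 3 of LS411N with doxycycline (adjusted p = 0.16 in each), without the TPM filter (0.42), with robust moderation (0.46) and over protein-coding genes (0.18). CXCR4, a chemokine receptor, fell from 9.92 ± 0.577 to 1.57 ± 0.154 TPM and LCK, a kinase of the SRC family, from 5.5 ± 0.608 to 0.636 ± 0.0308 TPM. AZGP1 fell from 83.3 ± 13.6 to 25.9 ± 3.57 TPM and TNFRSF11B, a decoy receptor, from 8.82 ± 1.56 to 2.28 ± 0.604 TPM. MYB, a transcription factor of crypt progenitors with a word in its 3′ UTR, fell from 39.8 ± 7.56 to 12.7 ± 0.498 TPM. The adjusted p-values of these rises and falls were at most 5e-04 and 1.3e-11.

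In the colonocyte differentiation list 11 of 22 tested members rose (12 adjusted over the list alone, where 1 also fell), and the other 11 were not called. After rescaling 13 rose and 2 fell. Its median lay 0.33 above that of all genes (camera adjusted p = 2e-12, and with an estimated correlation adjusted p = 0.94). Besides FABP1 and KRT20, CEACAM6, a cell adhesion protein, rose from 8.2 ± 1.05 to 32.3 ± 1.25 TPM. Among epithelial junctions and keratins 9 of 35 rose (10 adjusted over the list alone, and 17 up and 2 down after rescaling), with the keratin KRT19 at log2 fold change 1.4 ± 0.15 SE and the intestinal cadherin CDH17 from 79.8 ± 21.4 to 155 ± 7.39 TPM. That list was higher by camera (adjusted p = 0.00016, with an estimated correlation adjusted p = 0.94).

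In the stem cell and pluripotency list 7 of 26 members rose and 8 fell (9 and 10 adjusted over the list alone, 9 and 12 after rescaling), and its median lay 0.16 below that of all genes. OLFM4, a crypt-base glycoprotein, fell from 12.5 ± 2.11 to 3.68 ± 0.268 TPM, while ALDH1A3, a retinal dehydrogenase, rose from 18.1 ± 2.62 to 42.8 ± 1.84 TPM. Camera called the list lower (adjusted p = 0.016, with an estimated correlation adjusted p = 0.94), and median-of-ratios rescaling ended the call (adjusted p = 0.22) while the median stayed low (-0.14, all genes 0.01). In the WNT target list 4 of 24 rose and 8 fell (5 and 11 adjusted over the list alone, 8 and 12 after rescaling), and the median lay 0.31 below. The Ephrin receptors EPHB2 and EPHB3 fell from 17.4 ± 1.46 to 9.34 ± 0.706 TPM and from 35.5 ± 5.65 to 17.4 ± 1.1 TPM, and the growth factor co-receptor TDGF1 from 6.17 ± 0.656 to 2.87 ± 0.261 TPM. This list was lower (camera adjusted p = 0.0014, with an estimated correlation adjusted p = 0.94).

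Genes of drug handling rose in LS411N: 8 of 14 tested members of the drug efflux and detoxification list (11 adjusted over the list alone, and 11 after rescaling), the other 6 not called. The efflux pump ABCC2 rose from 2.64 ± 0.388 to 8.71 ± 0.717 TPM, ABCG2 from 9.31 ± 1.13 to 19.8 ± 1.16 TPM and the drug-oxidising enzyme CYP3A5 from 6.2 ± 1 to 16.7 ± 0.513 TPM, the last 2 with a word in their 3′ UTR. The list median lay 0.35 above (camera adjusted p = 1.8e-07, with an estimated correlation adjusted p = 0.94). Among NRF2 targets 10 of 30 rose (16 adjusted over the list alone, where 1 also fell, and 15 up and 3 down after rescaling), with AKR1B10, a carbonyl reductase, from 0.743 ± 0.119 to 3.66 ± 0.243 TPM and OSGIN1 from 1.01 ± 0.0803 to 1.74 ± 0.18 TPM (camera adjusted p = 0.0027, with an estimated correlation adjusted p = 0.94). Without replicate 1 of LS411N with doxycycline OSGIN1 was not called (adjusted p = 0.093).

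Cell cycle inhibitors and p53 targets were higher, with 8 of 27 members up and 1 down (9 and 2 adjusted over the list alone, 10 and 2 after rescaling). The inhibitor CDKN1A rose from 7.22 ± 0.644 to 21.8 ± 1.58 TPM, CDKN2B, with a word, from 2.78 ± 0.391 to 4.96 ± 0.531 TPM, and the stress cytokine GDF15 from 111 ± 16.5 to 183 ± 16 TPM. Camera gave adjusted p = 0.04, with an estimated correlation adjusted p = 0.94, and the call ended with rescaling and with a replicate block, the replicate number as covariate (adjusted p = 0.056 in each), and without replicate 3 of LS411N without doxycycline (adjusted p = 0.32). Of goblet, secretory and enteroendocrine markers 7 of 14 rose and 1 fell (8 and 2 adjusted over the list alone, 7 and 2 after rescaling), with the tuft cell factor POU2F3 at log2 fold change 1.1, GALNT5 at 1.07 and AGR3 at 1.04. The list was higher (camera adjusted p = 0.0039, with an estimated correlation adjusted p = 0.94), a call that ended with rescaling (0.065) and without that replicate (adjusted p = 0.39). In the apoptosis and BCL2 family list 4 of 21 rose (5 adjusted over the list alone, and 7 up and 1 down after rescaling), among them BIRC3 (0.83), the death receptor FAS (0.53) and BAD (0.43). It was higher too (camera adjusted p = 0.023, with an estimated correlation adjusted p = 0.94), but not after rescaling (adjusted p = 0.051) or with a replicate block (adjusted p = 0.05 as rounded). The medians of these 3 lists after rescaling were 0.08, 0.34 and 0.16, against 0.07, 0.33 and 0.16 above all genes as deposited. Without the TPM filter BIRC3, FAS and BAD were not called (adjusted p = 0.054, 0.063 and 0.064). BAD was also lost with a replicate block (adjusted p = 0.16) and on leaving out any of 5 of the 6 libraries (up to 0.32), all but replicate 3 without doxycycline.

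Cell cycle and DNA replication genes, ribosomal proteins and histones were called lower as lists without single calls, and other splits of the libraries gave as small an adjusted p for each. Of 48 cell cycle genes, limma called 0 higher and 0 lower, 3 and 4 at an unadjusted p under 0.05, and 3 and 21 after rescaling. The list was lower (camera adjusted p = 0.025, with an estimated correlation adjusted p = 0.94), except without replicate 3 of LS411N without doxycycline (adjusted p = 0.093) and with a replicate block (adjusted p = 0.058). Of 50 ribosomal proteins 0 were called by limma, 1 was lower at an unadjusted p under 0.05 and 10 were lower after rescaling, with a median 0.13 below (camera adjusted p = 0.015, with an estimated correlation adjusted p = 0.94). Of 6 histones 0 were called by limma, 2 were lower at an unadjusted p under 0.05 and 5 were lower after rescaling, with a median 0.33 below (camera adjusted p = 0.015, with an estimated correlation adjusted p = 0.94). With a replicate block the histones were not called (adjusted p = 0.05 as rounded). Among chromatin remodelling and polycomb genes 3 of 36 fell (1 adjusted over the list alone, and 1 up and 13 down after rescaling): DNMT3A (-0.48), MBD3 (-0.42) and ARID2 (-0.43), all with a word. That list was lower (camera adjusted p = 0.021, with an estimated correlation adjusted p = 0.94), and 15 of its 36 tested members hold a word, without which the adjusted p was 0.3. A replicate block also ended the call (0.05 as rounded). Without the TPM filter DNMT3A, MBD3 and ARID2 were not called (adjusted p = 0.1, 0.1 and 0.2), and a replicate block ended the last 2 (0.17 and 0.16). Without replicate 3 of LS411N with doxycycline all 3 were lost (0.13, 0.19 and 0.25). Without replicates 1 and 2 of that group MBD3 (0.11 and 0.21) and ARID2 (0.14 and 0.15) were lost, and MBD3 also without replicate 2 of LS411N without doxycycline (0.068).

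Camera called none of the remaining 17 lists in LS411N. For ERK output, the transcripts that follow ERK kinase activity, adjusted p was 0.15 (0.019 and higher without the genes that hold a word), with 8 of 24 members up and 2 down (9 and 2 adjusted over the list alone, 10 and 2 after rescaling). The ERK phosphatase DUSP5 rose by 1.57 and EPHA2 by 0.92 on the log2 scale, and the potassium channel KCNN4 fell by 0.91. Receptor tyrosine kinases, adaptors and ligands (adjusted p = 0.16) had 8 of 27 up and 1 down (8 and 4 after rescaling), with the EGFR ligand AREG up by 0.95 and FGFR4 down at -0.85. RAS, RAF, MEK, ERK and PI3K, AKT, mTOR kinases (adjusted p = 0.27) had 3 of 25 up (7 up and 3 down after rescaling). For type I interferon response (adjusted p = 0.13) 7 of 22 rose and 2 fell (9 and 4 after rescaling), with OAS1 at 1.56, OAS3 at 0.8 and BST2 at -0.86, the last not called without the TPM filter (adjusted p = 0.069). Hypoxia and glycolysis (adjusted p = 0.61) had 5 of 36 up and 4 down (10 and 7 after rescaling), with PGAM1 at -1.19 and LDHA at -0.67, both with a word, and NDRG1 at 0.6. Mucins and mucin glycosylation (adjusted p = 0.29) had 6 of 18 up and 2 down (8 and 4 after rescaling), with the glycosyltransferase GCNT3 at 1.46 and LGALS3 at 1.31. Heat shock and immediate early genes (adjusted p = 0.16) had 7 of 19 up (5 up and 5 down after rescaling), with KLF6 at 0.96, JUNB at 0.77 and DUSP1 at 0.58. The adjusted p was 0.23 for NF-kB signalling, 0.34 for antigen presentation, 0.39 for ATF4 and integrated stress response, and 0.59 for MYC targets, mesenchymal genes and cholesterol synthesis alike. It was 0.65 for the unfolded protein response, 0.61 for the mitochondrial ribosome, 0.91 for nuclear oxidative phosphorylation and 0.29 for DNA repair. Fibroblast and endothelial markers, immune cell markers and mitochondrially encoded genes had too few tested members for a test, with 0, 2 and 0.

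No list in LS411N was called with an estimated correlation in camera, and 0 of 30 reached an unadjusted p under 0.05. Of the 10 splits of the 6 libraries, the real one counted, 4 gave an adjusted p as small as the real one for cell cycle (smallest other 0.0027) and ribosomal proteins (3.1e-09), and 3 for chromatin (0.0092) and histones (0.0042). For p53 targets (0.037) and goblet markers (0.00015) 2 did, and for the other 7 called lists the real split alone. These 7 were each also called in another split. The margin was narrow for epithelial junctions (0.00016 against 0.00017), stem cell factors (0.016 against 0.038) and apoptosis (0.023 against 0.036). It was wider for colonocyte differentiation (2e-12 against 2.1e-05). Every library with doxycycline also carried the induced hairpin, so the effect of the drug itself is not separated from that of the hairpin.

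**Figure D2:**
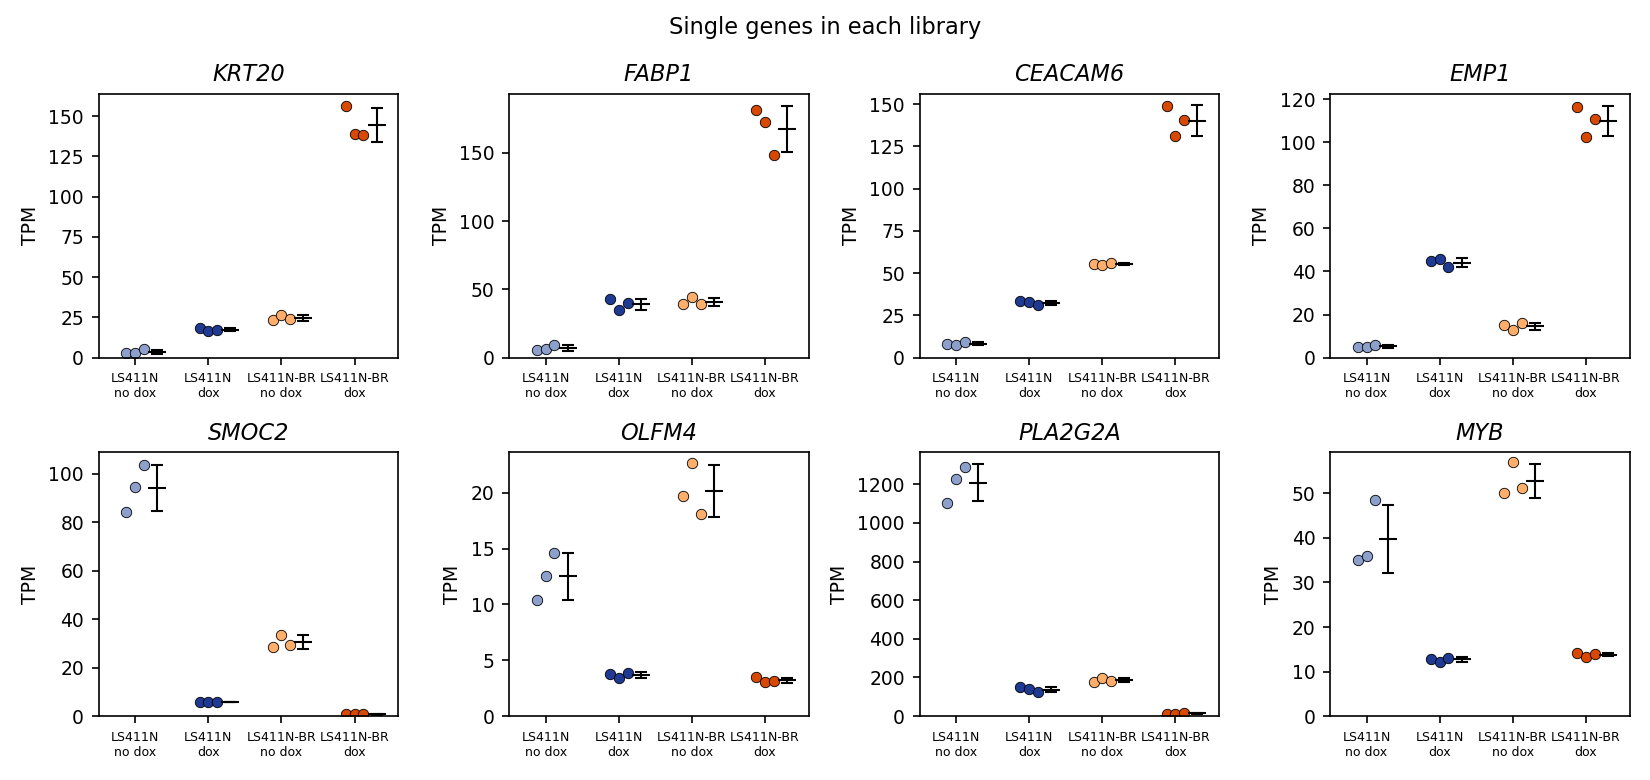
TPM (vertical axes, from 0) of 8 named genes in each library, by line and doxycycline. Points are libraries, and the bars beside them are the mean and SD of 3 libraries. KRT20, FABP1, CEACAM6 and EMP1 were higher with doxycycline in both lines, and SMOC2, OLFM4, PLA2G2A and MYB were lower.

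The second comparison asked the same in LS411N-BR, where 26 of 28 colonocyte differentiation genes rose. KRT20 rose from 24.7 ± 1.82 to 145 ± 10.3 TPM (log2 fold change 2.5 ± 0.06 SE), FABP1 from 41 ± 3.03 to 167 ± 17.1 TPM and EMP1 from 14.6 ± 1.58 to 110 ± 7.06 TPM. SMOC2 fell from 30.5 ± 2.81 to 0.783 ± 0.165 TPM (-4.14 ± 0.07 SE), OLFM4 from 20.1 ± 2.33 to 3.22 ± 0.228 TPM and PLA2G2A from 185 ± 10.2 to 13.4 ± 0.333 TPM. After median-of-ratios rescaling the adjusted p-values of KRT20 and SMOC2 were 2.3e-10 and 6.7e-11.

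Of 11322 genes tested in LS411N-BR, 6351 were called higher and 1252 lower, 171 and 57 by at least 2-fold. The median over all tested genes was 0.18, and short RNA genes fell from 53.5% ± 1.03 to 49.7% ± 2.1 of the TPM. With median-of-ratios rescaling the median was 0, and 3653 genes were higher and 3644 lower, so the share of calls that were higher went from 83.5 to 50.1%. Under both scalings 3652 genes were called higher and 1239 lower, and 1 gene was called in opposite directions. At least 2-fold higher or lower under both scalings were 95 and 57 genes.

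The other genes with the largest rises in LS411N-BR were PKIB, a protein kinase A inhibitor with a word (1.85 ± 0.21 to 25.4 ± 0.787 TPM), PI3 (10.8 ± 0.423 to 75.7 ± 9.74 TPM) and PLAC8 (8.2 ± 0.482 to 41.6 ± 2.63 TPM). GUCA2A, the guanylin precursor of mature colonocytes, rose from 2.23 ± 0.745 to 12.5 ± 0.982 TPM and TM4SF4 from 2.48 ± 0.106 to 13.5 ± 1.89 TPM. REG1A, a secreted lectin, fell from 49.4 ± 6.83 to 6.31 ± 0.513 TPM and SPINK4, a goblet cell peptide, from 23.1 ± 2.85 to 4.15 ± 0.975 TPM. MYB, with a word, fell from 52.7 ± 3.79 to 13.8 ± 0.403 TPM, KIAA1324 from 13 ± 1.28 to 2.99 ± 0.124 TPM, and WARS, a tRNA synthetase with a word, from 64 ± 1.42 to 18.5 ± 1.27 TPM.

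Colonocyte differentiation was the list with the largest shift: 26 of 28 tested members rose, also adjusted over the list alone, and 2 were not called (23 up and 2 down after rescaling). Its median lay 0.89 above that of all genes (camera adjusted p = 2.4e-32, with an estimated correlation adjusted p = 0.41). Of epithelial junctions and keratins 28 of 35 rose and 1 fell, also adjusted over the list alone (21 and 6 after rescaling), with KRT19 from 164 ± 4.71 to 419 ± 11.7 TPM and plakoglobin (JUP) from 60.9 ± 1.46 to 113 ± 8.21 TPM (camera adjusted p = 3e-05, with an estimated correlation adjusted p = 0.92). Drug efflux and detoxification genes rose in 13 of 15 cases and fell in 1, also adjusted over the list alone (10 and 2 after rescaling). ABCG2, with a word, went from 19.8 ± 1.39 to 57.4 ± 2.5 TPM, the glucuronosyltransferase UGT1A1 from 2.13 ± 0.243 to 8.8 ± 1.34 TPM and CYP3A5, with a word, from 10.5 ± 0.246 to 29.6 ± 2.03 TPM. That list's median lay 0.39 above (camera adjusted p = 4.9e-06, with an estimated correlation adjusted p = 0.89).

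ERK output was higher in LS411N-BR, which grew in BRAF inhibitor: 17 of 23 members rose and 5 fell, also adjusted over the list alone (13 and 6 after rescaling). DUSP5 rose from 22.4 ± 0.796 to 83.5 ± 2.27 TPM and cyclin D1 (CCND1) from 57.1 ± 3.01 to 107 ± 6.53 TPM, while SPRY2, an inhibitor of receptor signalling with a word, fell from 17.7 ± 0.981 to 7.77 ± 0.258 TPM. The list's median lay 0.23 above (camera adjusted p = 0.024, with an estimated correlation adjusted p = 0.92), and rescaling ended the call (adjusted p = 0.053) with the median at 0.24 and that of all genes at 0. Heat shock and immediate early genes rose in 16 of 18 cases, also adjusted over the list alone (11 up and 1 down after rescaling), with KLF6 at log2 fold change 1.15, FOS at 0.86 and NR4A1 at 0.81 (camera adjusted p = 0.0018, with an estimated correlation adjusted p = 0.92). Type I interferon response had 18 of 22 members up and 2 down, also adjusted over the list alone (14 and 3 after rescaling), with ISG15 at 1.53, OAS1 at 1.37 and OASL at 1.3 (camera adjusted p = 0.014, with an estimated correlation adjusted p = 0.92). Without the genes that hold a word the adjusted p of the interferon list was 0.058. Apoptosis and BCL2 family genes had 18 of 21 up and 1 down, also adjusted over the list alone (13 and 2 after rescaling), with FAS at 0.76 and BIRC3 at 0.66 (camera adjusted p = 0.044, with an estimated correlation adjusted p = 0.92).

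The stem cell and pluripotency list was called lower although 13 of its 25 members rose and 9 fell, also adjusted over the list alone (9 and 12 after rescaling). Its median was 0.14, while its mean was -0.15, with SMOC2 and OLFM4 far below and KLF4, a differentiation factor of the gut, up from 28.1 ± 1.82 to 84 ± 3.94 TPM (camera adjusted p = 0.00017, with an estimated correlation adjusted p = 0.92). WNT targets were lower with a median of 0.05 and a mean of -0.06: 9 of 21 rose and 8 fell, also adjusted over the list alone (7 and 11 after rescaling). EPHB3 fell from 15.3 ± 1.28 to 5.18 ± 0.116 TPM and TDGF1 from 4.58 ± 0.308 to 1.04 ± 0.0612 TPM, while CCND1 rose (camera adjusted p = 0.014, with an estimated correlation adjusted p = 0.92). Goblet, secretory and enteroendocrine markers were lower, with 7 of 16 up and 8 down, also adjusted over the list alone (6 and 9 after rescaling). SPINK4 and ATOH1, the factor that sets secretory fate (2.57 ± 0.439 to 0.155 ± 0.0347 TPM), fell and POU2F3 rose from 1.17 ± 0.0969 to 5.09 ± 0.401 TPM (camera adjusted p = 0.0061, with an estimated correlation adjusted p = 0.89). Rescaling ended the calls of these 3 lists (adjusted p = 0.3, 0.21 and 0.45). Their medians relative to all genes were -0.04, -0.13 and -0.22 as deposited and -0.06, -0.12 and -0.23 after rescaling.

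Camera called the hypoxia and glycolysis, ATF4 and unfolded protein response lists lower in LS411N-BR, with members called in both directions in each. Of the 10 splits of the 6 libraries, the real one counted, 4, 4 and 5 gave an adjusted p as small, down to 5.8e-09, 0.00036 and 0.0068, so these calls are not set apart from other groupings. In the hypoxia and glycolysis list 11 of 36 rose and 15 fell, also adjusted over the list alone (6 and 23 after rescaling), with the hypoxia marker CA9 from 12.6 ± 0.714 to 4.26 ± 0.97 TPM. The glycolytic enzymes PGAM1 and LDHA, both with a word, went from 130 ± 4.57 to 63.3 ± 3.27 and from 424 ± 19.2 to 266 ± 7.17 TPM. The list median lay 0.23 below (camera adjusted p = 5.3e-05, with an estimated correlation adjusted p = 0.92). In the ATF4 and integrated stress response list 10 of 28 rose and 8 fell, also adjusted over the list alone (4 and 16 after rescaling). WARS, whose fall is given above, is listed under its newer symbol and was not matched, so these counts leave it out. NUPR1 fell from 20.4 ± 1.91 to 8.36 ± 1.45 TPM and the cystine transporter SLC7A11, with a word, from 21.4 ± 0.728 to 12.6 ± 0.547 TPM, while ATF3 rose from 5.38 ± 0.156 to 9.64 ± 0.724 TPM. Camera called it lower with a median of 0.05, which is -0.13 relative to all genes, and a mean of -0.02 (adjusted p = 0.014, with an estimated correlation adjusted p = 0.92). The unfolded protein response list, with 6 of 24 up and 7 down, also adjusted over the list alone (3 and 16 after rescaling), was lower too (camera adjusted p = 0.035, with an estimated correlation adjusted p = 0.92). Its members ATF6 and SDF2L1 rose by 0.47 and 0.34 and SEL1L fell by 0.41 on the log2 scale.

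All 6 tested histones fell, also adjusted over the list alone, with HIST1H2AC from 618 ± 24.4 to 360 ± 13.9 TPM, HIST1H1C from 1360 ± 49 to 863 ± 33.1 TPM and HIST1H2BD from 437 ± 24.3 to 284 ± 9.8 TPM (camera adjusted p = 7.9e-08, with an estimated correlation adjusted p = 0.41). Of ribosomal proteins 4 of 50 rose and 6 fell (3 and 3 adjusted over the list alone), but 0 rose and 39 fell after rescaling. RPL7 and RPLP2 fell by 0.27 and 0.25, the latter not called without the TPM filter (adjusted p = 0.082) or with a spread from all 12 libraries (0.095). RPL18 rose by 0.23 as deposited and by 0.03 after rescaling, where it was not called (adjusted p = 0.81), as also without replicate 1 of LS411N-BR with doxycycline (adjusted p = 0.11), without the TPM filter (0.18), with a spread from all 12 libraries (0.11) and over protein-coding genes (0.46). Camera called the list lower with a median of 0.02, which is -0.17 relative to all genes (adjusted p = 0.0094, with an estimated correlation adjusted p = 0.92). However, 7 of the 10 splits gave an adjusted p as small, down to 2.8e-08. Of chromatin remodelling and polycomb genes 14 of 36 rose and 7 fell, also adjusted over the list alone, and 3 and 20 did so after rescaling. RNF2 was at 0.51, EZH1 at 0.42 and ARID2, with a word, at -0.33. The list was lower with a median of 0.03, which is -0.15 relative to all genes (camera adjusted p = 0.046, with an estimated correlation adjusted p = 0.92). Without the 15 members that hold a word the adjusted p was 0.23.

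Camera called none of the remaining 14 lists in LS411N-BR. Cell cycle and DNA replication genes (adjusted p = 0.1, and 0.00024 and lower after rescaling) were higher in 17 and lower in 2 of 48 cases as deposited (12 and 0 adjusted over the list alone), but higher in 1 and lower in 31 after rescaling. MCM10, MCM3 and E2F2 rose by 0.31, 0.25 and 0.27 as deposited, and the last 2 were not called after rescaling (adjusted p = 0.21 and 0.065). MCM3 was also lost with a spread from all 12 libraries (0.064) and over protein-coding genes (0.06). Cell cycle inhibitors and p53 targets (adjusted p = 0.16) had 19 of 28 up and 4 down (12 and 7 after rescaling), with CDKN1A from 17.9 ± 0.39 to 61.7 ± 3.63 TPM, CDKN2B, with a word, at 1.05 and TP53I3 at 0.94. Receptor tyrosine kinases, adaptors and ligands (adjusted p = 0.17) had 18 of 26 up and 3 down (16 and 8 after rescaling), with AREG at 1.11, EPHA2 at 0.93 and FGF2, with a word, at 1. RAS, RAF, MEK, ERK and PI3K, AKT, mTOR kinases (adjusted p = 0.18) had 19 of 25 up and 2 down (15 and 5 after rescaling), with DUSP1 at 0.79 and MAPK3 at 0.57. Mucins (adjusted p = 0.11, and 0.034 and higher without the 7 members that hold a word) had 14 of 19 up and 4 down (12 and 5 after rescaling), with MUC17 at 1.71 and LGALS3 at 1.23. NRF2 targets (adjusted p = 0.58) had 20 of 30 up and 5 down (13 and 10 after rescaling), with ABCC2 at 1.45 and HMOX1 at 0.91. MYC targets (adjusted p = 0.39) had 26 of 36 up and 1 down (13 and 8 after rescaling), with SRM at 0.79 and NOP16 at 0.52.

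In LS411N-BR the mitochondrial ribosome list (adjusted p = 0.92) had 23 of 35 up and 2 down as deposited and 8 up and 12 down after rescaling, with MRPL17, which holds a word, at -0.61, CLPP at 0.47 and MRPL20 at 0.44. Nuclear oxidative phosphorylation genes (adjusted p = 0.39) had 17 of 38 up and 4 down, and 3 up and 15 down after rescaling, with NDUFA1 and NDUFV2 at 0.38 and NDUFA4 at 0.34. Cholesterol and fatty acid synthesis (adjusted p = 0.89) had 20 of 34 up and 4 down, and 13 each after rescaling, with SC5D at 0.68, ELOVL6, with a word, at 0.49 and ACAT2 at 0.48. DNA repair (adjusted p = 0.18, and 0.031 and lower after rescaling) had 12 of 34 up and 3 down, and 5 up and 17 down after rescaling, with FANCD2 at -0.38, LIG4 at 0.38 and PARP2 at 0.33. NF-kB signalling (adjusted p = 0.84) had 16 of 27 up and 4 down (10 and 7 after rescaling), with NFKBIZ at 0.81 and IL32 at 0.54. Antigen presentation (adjusted p = 0.3) had 4 of 13 up and 3 down (2 and 5 after rescaling), with B2M, which holds a word, at 0.57, HLA-E at 0.28 and ERAP1 at -0.29, the last not called with a spread from all 12 libraries (adjusted p = 0.05 as rounded). For mesenchymal genes adjusted p was 0.67, with 3 of 8 up and 1 down as deposited and 1 up and 4 down after rescaling, where the camera direction turned from up to down. Fibroblast and endothelial markers had 1 tested member and immune cell markers 2.

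With an estimated correlation 0 of 30 lists in LS411N-BR were called by camera, and 2 reached an unadjusted p under 0.05. Besides the 4 lists with split counts above, an adjusted p as small came in 3 of 10 splits for chromatin (smallest other 0.00029) and apoptosis (0.014) and in 2 for goblet markers (2.1e-05), and for the other 9 called lists in the real split alone. Of these 9, all but WNT targets (smallest other 0.053) and drug efflux (0.086) were also called in another split. The margin was narrow for ERK output (0.024 against 0.026) and interferon response (0.014 against 0.024). The share of called genes in this line rests on a spread taken from the trend alone.

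**Figure D3:**
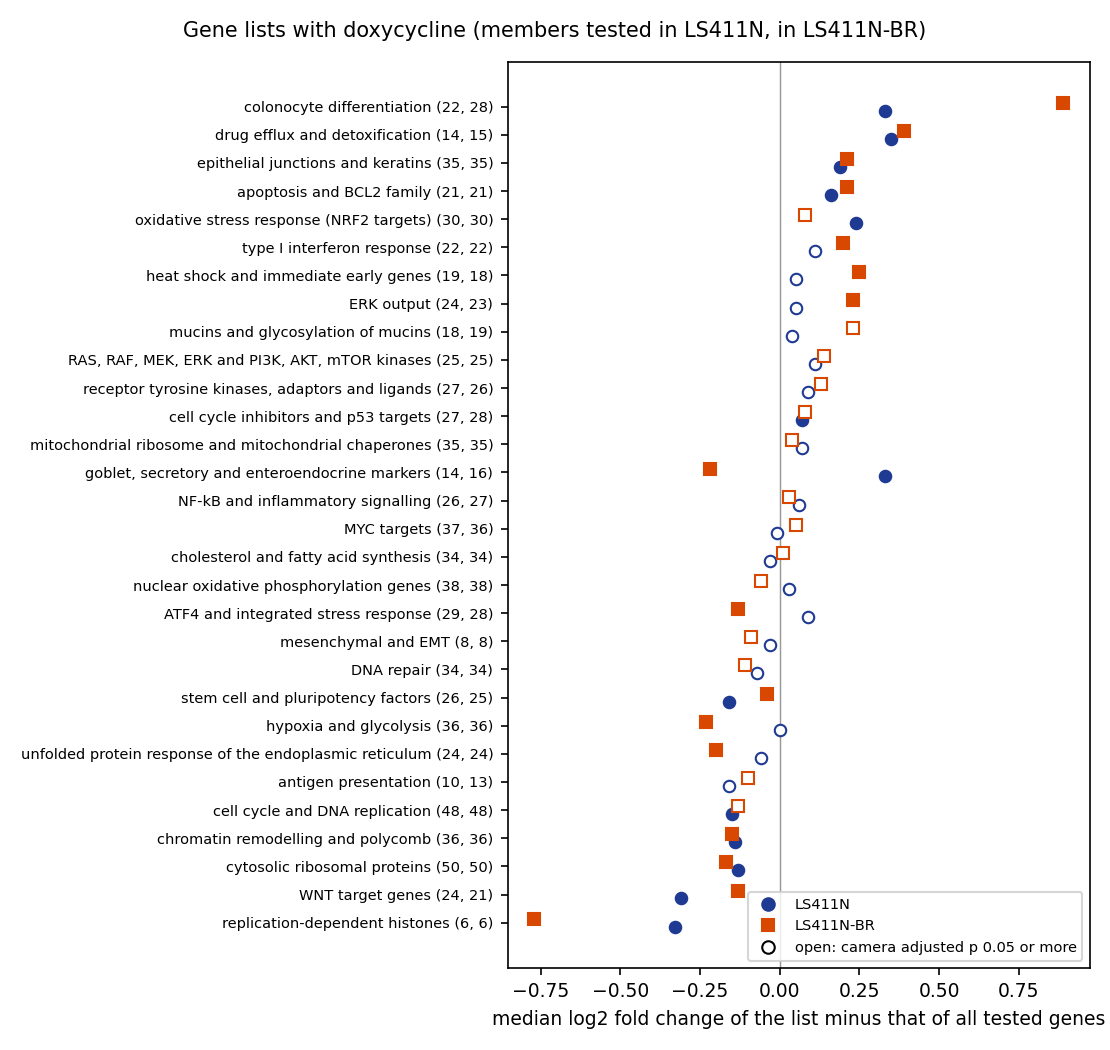
Median log2 fold change with doxycycline of 30 gene lists minus that of all tested genes (horizontal axis), in LS411N (circles) and LS411N-BR (squares). Filled symbols have a camera adjusted p under 0.05 at the preset correlation, and numbers after each name are the members tested in LS411N and LS411N-BR. Colonocyte differentiation lies at 0.33 and 0.89, and histones at -0.33 and -0.77.

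The third comparison asked how far the lines shared their calls. Of 10935 genes tested in both, 1012 were called higher in both, among them EMP1, ANXA1, KRT20 and FABP1, where 587.8 would be expected if the calls were independent (ratio 1.72, Fisher's exact p = 3.52e-217). A further 301 were lower in both, among them MUC1, SMOC2, PLA2G2A, OLFM4 and MYB, against 37.2 expected (ratio 8.09, Fisher's exact p = 1.04e-255). Fisher's test takes genes as independent units, which they are not, so these p-values do not measure replication between the lines. By at least 2-fold 67 were higher and 23 lower in both. Of the genes lower in both that had a searched 3′ UTR, 144 of 278 (51.8%) hold a word. The shares were 15.4% of 926 higher in both and 21.4% of all 10053 tested in both with such a UTR. The words were picked by fold changes of the same libraries, so these shares describe that choice and do not test it. As deposited 10 genes were higher in LS411N and lower in LS411N-BR and 6 the other way, and after rescaling 41 and 20. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.82 and a Spearman rho of 0.79. With median-of-ratios rescaling 1749 genes were higher and 1501 lower in both. Without replicate 3 of LS411N without doxycycline the shared counts were 4818 and 511, and leaving out other LS411N libraries gave 483 to 576 higher and 136 to 311 lower.

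**Figure D4:**
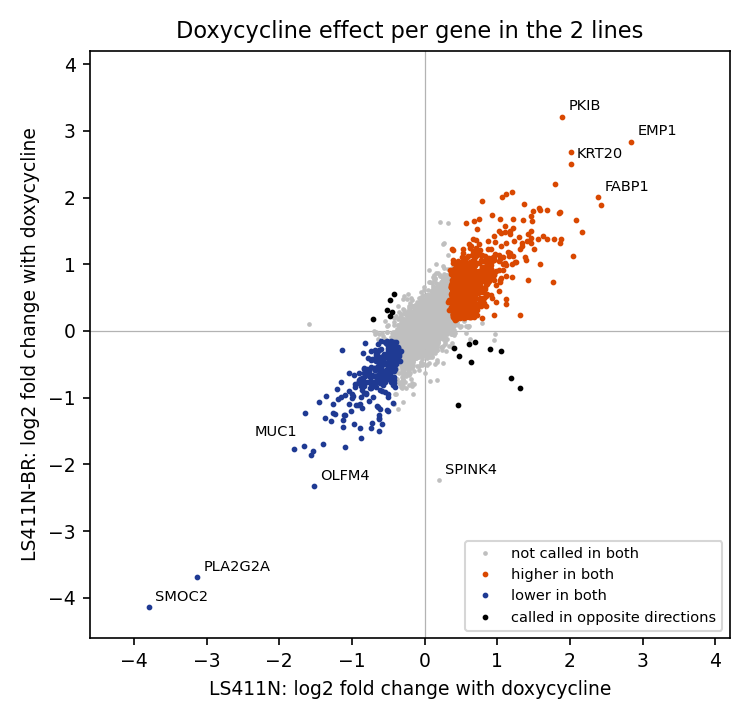
Log2 fold change with doxycycline in LS411N (horizontal axis) against that in LS411N-BR (vertical axis), with 1 point per gene for the 10935 genes tested in both. Orange and blue points are the 1012 and 301 genes called higher and lower in both lines, and black points the 16 called in opposite directions.

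The fourth comparison tested the difference itself. SPINK4 was 22.6 ± 2.9 and 26.2 ± 4.05 TPM without and with doxycycline in LS411N, but fell in LS411N-BR (difference of log2 fold changes -2.44 ± 0.19 SE, adjusted p = 7.2e-08). REG4, a goblet cell lectin with a word, was 22 ± 4.67 and 30.2 ± 3.44 TPM in LS411N and 17.8 ± 0.427 and 7.71 ± 0.286 TPM in LS411N-BR (-1.57 ± 0.17 SE, adjusted p = 3.8e-06). CEACAM1, an adhesion protein of mature epithelium, was 4.4 ± 0.68 and 5.2 ± 0.285 TPM in LS411N and 10.1 ± 0.27 and 33.4 ± 1.32 TPM in LS411N-BR (1.43 ± 0.13 SE, adjusted p = 7.6e-07). TNFRSF11B fell in LS411N and was 2.08 ± 0.12 and 2.31 ± 0.165 TPM in LS411N-BR (1.69 ± 0.17 SE, adjusted p = 1.5e-06).

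Of 11674 genes tested for the difference, 162 had a higher doxycycline effect in LS411N-BR and 85 a lower one, 28 and 17 by at least 2-fold. The median over all genes was 0.11. With median-of-ratios rescaling 512 were higher and 751 lower, so the share that was higher went from 65.6 to 40.5%, and 160 and 84 genes were called in the same direction under both scalings. Without replicate 3 of LS411N without doxycycline 471 were higher and 593 lower. Leaving out any of the other 11 libraries gave 88 to 260 higher and 54 to 87 lower.

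Other genes with large differences were TFF1, a trefoil peptide, 11 ± 2.58 and 21.3 ± 3.17 TPM in LS411N and 4.73 ± 0.238 and 3.8 ± 1.01 TPM in LS411N-BR (-1.17, not called without the TPM filter, adjusted p = 0.074), and SERPINI1, with a word, 0.747 ± 0.204 and 0.634 ± 0.0861 TPM against 9.76 ± 1.15 and 3.38 ± 0.597 TPM (-1.21). Some rest on genes near 0 TPM in 1 line. CXCR4 fell in LS411N and was 0.589 ± 0.103 and 0.285 ± 0.0574 TPM in LS411N-BR (1.78). CEACAM7 was 0.0631 ± 0.0176 and 0.402 ± 0.0269 TPM in LS411N and 2.83 ± 0.2 and 14.6 ± 1.63 TPM in LS411N-BR (1.62). REG1A was 0.419 ± 0.211 and 0.161 ± 0.162 TPM in LS411N (-2.49). With a pseudocount of 0.1 TPM the differences of CEACAM7, REG1A and MUC17 were 0.69, -1.82 and 0.89 and no longer called (adjusted p = 0.13, 0.089 and 0.098), so their size depends on the pseudocount.

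In the goblet, secretory and enteroendocrine list 1 of 17 members had a higher effect in LS411N-BR and 6 a lower one (2 and 6 adjusted over the list alone, 2 and 7 after rescaling), among them SPINK4, REG4 and SPDEF, a goblet cell factor (-1.02). Its median lay 0.34 below that of all genes (camera adjusted p = 3.5e-10, with an estimated correlation adjusted p = 0.29). Hypoxia and glycolysis genes were lower in 5 of 36 cases (10 adjusted over the list alone, 14 after rescaling), with NDRG1 at -0.8, DDIT4 at -0.61 and the angiogenic factor VEGFA at -0.52 (camera adjusted p = 7.3e-10, with an estimated correlation adjusted p = 0.78). ATF4 and integrated stress response genes were lower in 2 of 29 cases (5 adjusted over the list alone, 12 after rescaling), DDIT4 and SLC7A11 (-0.53, with a word), and the median lay 0.23 below (camera adjusted p = 6.8e-09, with an estimated correlation adjusted p = 0.7). The calls of DDIT4, VEGFA and SLC7A11 ended on leaving out any of 6, 7 and 10 of the 12 libraries, with adjusted p up to 0.1, 0.094 and 0.14, and with a replicate block (0.06, 0.18 and 0.15). SLC7A11 was also lost with a pseudocount of 0.1 TPM (0.062), without the TPM filter (0.07) and with a filter of 5 TPM (0.05 as rounded). Colonocyte differentiation genes were higher in 9 of 28 cases and lower in 1 (12 and 2 adjusted over the list alone, 11 and 5 after rescaling), with CEACAM7, CEACAM1 and MUC17 (1.38), and the median lay 0.14 above (camera adjusted p = 9.4e-07, with an estimated correlation adjusted p = 0.81). With a pseudocount of 0.1 TPM the adjusted p of that list was 0.036.

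Heat shock and immediate early genes were higher in 2 of 19 cases (3 adjusted over the list alone, 2 after rescaling), NR4A1 at 0.57 and EGR1 at 0.56, the latter not called after rescaling (adjusted p = 0.14). With a pseudocount of 0.1 TPM neither was called (0.061 and 0.065), and the calls ended on leaving out any of 5 and 10 of the 12 libraries (adjusted p up to 0.071 and 0.15). A replicate block (0.095) and no TPM filter (0.09) also ended the call of EGR1. Camera called that list higher (adjusted p = 0.00034, with an estimated correlation adjusted p = 0.7). NRF2 targets were higher in 1 of 30 cases and lower in 2, also adjusted over the list alone (1 and 8 after rescaling), with HMOX1 at 0.49, AKR1B10 at -0.66 and SLC7A11 (camera adjusted p = 0.00043, lower, with an estimated correlation adjusted p = 0.99). HMOX1 was not called with a pseudocount of 0.1 TPM (adjusted p = 0.26), with a replicate block (0.08) or without any 1 of 8 libraries (up to 0.086). Over protein-coding genes HMOX1, NR4A1 and EGR1 were not called (0.077, 0.07 and 0.12). Of 6 histones limma called 0, with 4 lower at an unadjusted p under 0.05 and 4 lower adjusted over the list alone (5 after rescaling, camera adjusted p = 1.1e-07, lower, with an estimated correlation adjusted p = 0.36). Of 24 unfolded protein response genes limma called 0, with 3 lower at an unadjusted p under 0.05 and 6 lower after rescaling (camera adjusted p = 0.0018, lower, with an estimated correlation adjusted p = 0.99). The smallest adjusted p of the other 22 lists was 0.074, for MYC targets, and that of ERK output was 0.56. Without the genes that hold a word camera called ERK output (0.016) and MYC targets (0.035) higher. Nuclear oxidative phosphorylation (adjusted p = 0.092) was called lower after rescaling (0.0031) and without replicate 3 of LS411N without doxycycline (0.019). With a pseudocount of 0.1 TPM MYC targets were called higher and the stem cell list lower (adjusted p = 0.032 each). With an estimated correlation camera called 0 of 30 lists for the difference, and 2 reached an unadjusted p under 0.05.

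The last comparison set the lines side by side without doxycycline, with TPM rescaled over shared genes and no test. REG1A was 49.4 ± 6.83 TPM in LS411N-BR and 0.532 ± 0.262 TPM in LS411N, the brush border peptidase ANPEP 20.1 ± 1 and 0.747 ± 0.0909 TPM, and KRT20 24.7 ± 1.82 and 4.63 ± 1.44 TPM. LYZ, which encodes lysozyme, was 151 ± 4.94 TPM in LS411N-BR and 3300 ± 481 TPM in LS411N, and the trypsinogens PRSS1 and PRSS2 were 0.536 ± 0.09 and 24.7 ± 6.44 TPM and 0.343 ± 0.14 and 57.1 ± 13.4 TPM. MUC1 was 3.97 ± 0.293 and 6.52 ± 1.25 TPM.

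Of 11485 genes, 65.4% had no overlap between the lines, where chance gives 10%, and the median log2 ratio of LS411N-BR to LS411N was -0.22. The 10% holds for a gene taken alone, and an offset shared by the genes of a table can separate many at once. A gap of at least 4-fold between the groups separated 20 genes higher in LS411N-BR and 49 higher in LS411N, or 33 and 32 with median-of-ratios rescaling. Others at the top in LS411N-BR were TMEM200A (14.1 ± 1.1 against 0.0472 ± 0.0118 TPM), TSPAN7 (49 ± 3.56 against 2.53 ± 0.306 TPM), the lipid transfer protein MTTP (7.98 ± 1.04 against 0.193 ± 0.0365 TPM), VAV3, HIST1H4K and TAB3-AS1. In LS411N they were PET100, IFI6 (16.2 ± 0.359 against 0.528 ± 0.0869 TPM), TESC, SMOC1 and SNRPF. Of 26 colonocyte differentiation genes 19 were higher in LS411N-BR without overlap (median log2 ratio 0.92), and of 29 ATF4 and integrated stress response genes 27 were higher in LS411N (median -0.97). A lean to LS411N was not particular to that list. All lists but colonocyte differentiation and mucins (0.05) had a median below 0, with 42 of 50 ribosomal proteins higher in LS411N (-0.79). Line, inhibitor in the medium and table went together, so these differences belong to all 3 at once.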

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

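Of the tests in this part, those of rescaling, of genes with a word, of doxycycline itself, of replicate 3 of LS411N without doxycycline and of inter-gene correlation (a setting fixed beforehand, turned to these patterns later) were chosen after the result was seen, and the counts over other splits were not. Each result below drew attention because the effect of doxycycline differed between the lines by the interaction test.

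Among single genes the difference of the log2 fold changes, LS411N-BR minus LS411N, was 1.78 for CXCR4, 1.69 for TNFRSF11B, 1.62 for CEACAM7 and 1.43 for CEACAM1. It was -2.49 for REG1A, -2.44 for SPINK4, -1.57 for REG4, -1.21 for SERPINI1 and -1.17 for TFF1. CEACAM7 and REG1A were at 0.69 and -1.82 with a pseudocount of 0.1 TPM and not called (adjusted p = 0.13 and 0.089), nor was TFF1 without the TPM filter (adjusted p = 0.074). Over all genes 247 were called for the difference, and 7 of 100 splits of the doxycycline labels within the lines called as many, the highest other split calling 6885. Chance is therefore not excluded for that count. All 7 keep the real doxycycline groups in a line, so a line's own response appears in them as a difference, and of the 82 splits that keep neither line's groups the highest called 0 genes. The split with 6885 calls points to this structure of the samples.

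Among gene lists, camera adjusted p for the difference was 9.4e-07 for colonocyte differentiation (higher in LS411N-BR), 3.5e-10 for goblet, secretory and enteroendocrine markers (lower), 7.3e-10 for hypoxia and glycolysis (lower) and 6.8e-09 for ATF4 and integrated stress response (lower). It was 0.0018 for the unfolded protein response (lower), 0.00043 for NRF2 targets (lower), 0.00034 for heat shock and immediate early genes (higher) and 1.1e-07 for histones (lower). With an estimated correlation the adjusted p, in the same order, was 0.81, 0.29, 0.78 and 0.7, then 0.99, 0.99, 0.7 and 0.36. In all 8 lists were called, and 51 of 100 splits called as many, the highest other split calling 16, so chance is not excluded for the number of lists. Of the 82 splits that keep neither line's groups, 35 called as many, up to 14. A p as small as the real one came in 9 of 100 splits for colonocyte differentiation and for histones, in 11 for the unfolded protein response and for heat shock, and in 4 for NRF2 targets. With the real split counted, all of the 9 and of the 4 keep a line's real groups, but only 2 of each 11 do.

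The first pattern weighed is that colonocyte differentiation genes were higher with doxycycline in both lines. The scaling of the libraries is argued against for the rise itself. After median-of-ratios rescaling the list medians were 0.34 in LS411N and 0.87 in LS411N-BR, against 0.01 and 0 over all genes. The larger of the 2 camera adjusted p was then 2.9e-06. That p alone does not set the calls apart from other groupings. Lists were not tested on other splits with rescaling, and as deposited another split of LS411N gave 2.1e-05. Correlation between the genes of the list may explain the calls, since with an estimated correlation adjusted p was 0.94 in LS411N and 0.41 in LS411N-BR. An effect through the genes that hold a word in their 3′ UTR stays open: without them the larger adjusted p was 1.1e-10, but only 4 tested members hold a word and such genes were lower, so leaving them out could hardly end a rise, and a route through other genes was not tested. Doxycycline acting independently of the hairpin stays open: it may act through stress of the mitochondria, but camera called the ATF4 list lower in LS411N-BR (adjusted p = 0.014, with an estimated correlation 0.92, 10 of 28 members up and 8 down, as small in 4 of 10 splits) and did not call it in LS411N (adjusted p = 0.39), and these cannot be told apart because every library with doxycycline also carries the induced hairpin. The loss of MUC1 itself stays open as a biological explanation and was not tested apart from the hairpin.

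The second pattern is that hypoxia, ATF4 and goblet lists moved apart between the lines. Replicate 3 of LS411N without doxycycline is argued against as the only source of the calls. Without it the largest of the 3 camera adjusted p was 1.5e-05. So is the scaling of the libraries (largest adjusted p = 0.00067 after median-of-ratios rescaling). The medians of the hypoxia, ATF4 and goblet lists were then -0.22, -0.25 and -0.29, against -0.01 over all genes. Lists were not tested on other splits under these settings, so these p alone do not set the calls apart from other groupings. Correlation between the genes of a list may explain the calls, since with an estimated correlation the smallest of the 3 adjusted p was 0.29. Each of the 3 lists had a p as small in 1 of 100 splits, the real one. A difference between the lines, or the inhibitor in the medium of LS411N-BR, stays open and was not tested.

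For the changes within a line, the 10 splits of 6 libraries are too few for a share under 0.05. In LS411N 1 of 10 splits, the real one, called as many as 1487 genes, and the highest other called 1. For lists 1 of 10 called as many as 13, and the highest other called 10. Taken singly, 6 of the 13 lists had an adjusted p as small in 2 to 4 of the 10 splits. In LS411N-BR 1 of 10 splits called as many as 7603 genes, and the highest other called 0. For lists 1 of 10 called as many as 16, and the highest other called 11. Taken singly, 7 of the 16 lists had an adjusted p as small in 2 to 7 of the 10 splits (goblet, hypoxia, ATF4, unfolded protein response, chromatin, apoptosis and ribosomal proteins). Genes called in the same direction in both lines numbered 1313, reached by 1 of 100 splits, with 16 in the highest other. Other splits within a line called at most 1 gene, so they had almost none to share. This count therefore cannot test whether the lines share calls beyond chance.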

How the results depend on the processing

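Rescaling over protein-coding or shared genes, median-of-ratios rescaling together with leaving out replicate 3 of LS411N without doxycycline, leaving out genes with a word, rescaling of the shared calls, and rescaling of the gene lists with an estimated correlation were chosen after the result was seen. Across all settings run, the log2 fold change of MUC1 lay between -2.34 and -1.54 in LS411N (largest adjusted p = 0.0041) and between -2.77 and -1.67 in LS411N-BR (largest adjusted p = 0.00014). Of 175 counts and values under settings other than left-out libraries, 118 were the same, and of 146 with a library left out 118 were. A count was the same within 1.5 times, and the MUC1 change within a line where its direction and call stayed. Of the named genes, 48 of 57 in LS411N, 84 of 89 in LS411N-BR and 9 of 20 for the difference kept direction and call under every setting that tested them. A filter of 5 TPM tested 47, 79 and 16 of the named genes, and leaving out genes with a word tested 48 and 74 within the lines.

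For genes called in LS411N (1100 higher, 387 lower), no filter gave 583 and 223, which tests more genes. Median-of-ratios rescaling gave 2126 and 1804, rescaling over protein-coding genes 2410 and 1532, a spread from all 12 libraries 1952 and 685, and rescaling without replicate 3 of LS411N without doxycycline 2824 and 2515. The replicate block gave 632 higher, a filter of 5 TPM 253 lower, and leaving out genes with a word 213 lower, the last 2 with fewer genes tested. Of those changed at least 2-fold (90 and 38), a pseudocount of 0.1 TPM gave 178 and 73, protein-coding rescaling 68 lower, and leaving out genes with a word 19 lower.

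For LS411N-BR (6351 higher, 1252 lower), median-of-ratios rescaling gave 3653 and 3644, protein-coding rescaling 3169 lower and a spread from all 12 libraries 722 lower. At least 2-fold (171 and 57) were 303 and 93 with a pseudocount of 0.1 TPM and 95 and 95 with median-of-ratios rescaling. Lower by at least 2-fold were 126 with protein-coding rescaling and 35 without genes with a word.

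For the difference (162 higher, 85 lower), a pseudocount of 0.1 TPM gave 59 and 50, a filter of 5 TPM 84 and 56, median-of-ratios rescaling 512 and 751, protein-coding rescaling 393 and 513, and rescaling without replicate 3 of LS411N without doxycycline 1029 and 1362. At least 2-fold higher (28) were 15 with a filter of 5 TPM and 18 with that last setting, and at least 2-fold lower (17) were 35 with protein-coding rescaling. The difference for MUC1, which was not called, reversed its sign to 0.05 with rescaling over shared genes and to 0.02 with rescaling without that replicate.

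Genes shared by the lines (1012 higher, 301 lower) were 67 and 23 at 2-fold or more, a stricter rule, 560 and 196 with the replicate block and 1749 and 1501 with median-of-ratios rescaling. With an estimated correlation camera called 0 lists in LS411N, 0 in LS411N-BR and 0 for the difference, where 0, 2 and 2 of 30 had an unadjusted p under 0.05. With median-of-ratios rescaling as well it also called 0, 0 and 0, where 3, 7 and 7 did. The replicate block gave 8 lists in LS411N in place of 13. Genes with a 4-fold gap between the lines (20 higher in LS411N-BR, 49 in LS411N) were 52 and 96 with a pseudocount of 0.1 TPM and 33 and 32 with median-of-ratios rescaling. Except for the filters, the 2-fold rule and the genes left out, the cause was not tested for any of these moves.

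With each library left out in turn, genes in LS411N were 523 to 5938 higher and 174 to 739 lower (87 to 104 and 28 to 48 by at least 2-fold), and MUC1 changed by -1.72 to -1.54. In LS411N-BR 5492 to 6714 were higher and 1015 to 1338 lower (149 to 190 and 55 to 67), and MUC1 changed by -1.81 to -1.67. The difference had 88 to 471 higher and 54 to 593 lower (25 to 38 and 14 to 21), the lines shared 483 to 4818 higher and 136 to 511 lower, and 4-fold gaps numbered 20 to 28 and 49 to 51. The highest count of each gene total that exceeded 1.5 times came without replicate 3 of LS411N without doxycycline.

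Not run were leaving out mitochondrially encoded genes, since the tables hold none, the trend, robust and replicate settings of the comparison between lines, and the reversal of line differences by doxycycline with its alternative, since no test between lines was run. Depth is not known, so its limit on genes with few TPM was not measured.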

Other observations

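Of the tests in this part, that of base composition was chosen after the result was seen, and the search for a shared word was not.

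The hypothesis was that genes lower with doxycycline in both lines are in part lowered by the induced hairpin RNA through matches of its seed in their 3′ UTRs. The lowest word was ATCAGTA in LS411N (t statistic -14.81) and TCAGTAA in LS411N-BR (t statistic -13.26), and these overlap by 6 bases. ATCAGTA occurs in MUC1 transcripts, as do 12.8% of all 16384 words, and TCAGTAA does not. Of 405 reorderings of the same bases the lowest had a t statistic of -4.26 over both lines. That none was as low was fixed beforehand in LS411N, where ATCAGTA was picked as the lowest word. In LS411N-BR only TCAGTAA was lower, and the reorderings left it out because it overlaps. Other orders of these bases thus had weaker statistics, but the test cannot decide on base composition of the 3′ UTRs. A seed effect of the hairpin is a candidate explanation for part of these genes. The hairpin sequence is not given in the sources used here, so the match to it was not tested.

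The 2 words joined, ATCAGTA followed by A, were present in the 3′ UTR of 410 genes tested in LS411N, whose median log2 fold change after median-of-ratios rescaling was -0.12, and of 409 in LS411N-BR, with a median of -0.13. Genes with ATCAGTA not followed by A had medians of -0.06 and -0.05, genes with TCAGTAA but not ATCAGTA -0.02 and -0.04, and genes with neither 0.03 and 0.01. The words were picked by these same fold changes, so the medians describe that choice and do not test it, and they are not adjusted for the length of the UTR. With length as a covariate, ATCAGTA, lowest in LS411N, had a t statistic of -13.16 in LS411N-BR, and TCAGTAA, lowest in LS411N-BR, one of -12.03 in LS411N. In MUC1-225 ATCAGTA lies in coding exon 5 of 8, on chromosome 1 from 155187772 to 155187778 (minus strand, GRCh38).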
